A study of Plutella xylostella with 6 samples.

How the data were processed

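Ovaries of the diamondback moth, Plutella xylostella, were profiled by RNA sequencing in 6 libraries, 3 from unmated and 3 from mated females, and the study gives the strain as Geneva88. The labels number the libraries of each group as biological replicates 1 to 3, but do not say how many animals were pooled in a library, how old the moths were or how long after mating the ovaries were taken. The p-values below therefore measure the spread between these libraries. Per the labels' protocols, total RNA was extracted with a kit from Promega and libraries were made with the NEBNext Ultra RNA kit for Illumina. Whether reads were counted by strand is not given in the sources used here, so reads of overlapping genes on opposite strands may not be separated.

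The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3, RSEM 1.3.3 and DESeq2 1.20.0, without saying which step each served. The deposited table holds values named as FPKM, which stands for fragments per kilobase of gene length and library size. It covers 16870 features in each library, together with gene descriptions, coordinates and lengths, per the file headers. The genome build is not given in the sources used here. The start and end of all 16283 features with a RefSeq gene identifier equal those of the RefSeq annotation of assembly ilPluXylo3.1, and chromosome numbers were taken from that annotation. The other 587 features are models without a RefSeq identifier. Gene symbols and descriptions are those of the deposited table. Of the features, 2714 had no read in any library.

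The deposited FPKM values were checked for the reads behind them. The product of FPKM and gene length was a whole multiple of a single step in each library for at least 99.99% of the values, within 0.02 of a read, so read numbers and depth could be recovered. The libraries held 10934960 to 12501272 recovered reads. The scaling implied by these steps equals median-of-ratios size factors computed from the recovered reads (largest difference 6.70e-08), so the deposited FPKM values were already scaled between libraries by a size factor, and not by each library's own total. The size factors were 0.939, 0.808 and 0.996 in the unmated and 1.14, 1.09 and 1.14 in the mated libraries. FPKM values were assumed when the design was written. The table held reads per kilobase scaled by size factors, and the name FPKM is kept for them here.

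Values were transformed as log2(FPKM + 1), and the 8406 features with a mean FPKM of at least 1 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. A second count required an absolute log2 fold change of at least 1. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. In groups of 3 against 3, a two-sided exact permutation test cannot go below p = 0.1, and that test was run beside limma for the genes fixed in advance. The same fit was tested on simulated data drawn from the real means and depths, with 200 changed genes. Of these 64, 67 and 61, changed 1.5-, 2- and 4-fold, were among the 8407 tested genes. The fit recovered 48.4%, 89.6% and 100% of them, and called 16 of 8215 unchanged genes. The simulation drew each gene independently, with the same spread between libraries for all genes and both groups. Real genes can move together and far more of them were called, so these rates need not hold for the real data.

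The choice of tests, the gene lists and the rule for named genes were set before the data were examined. The 27 lists were defined by words in gene descriptions. They were pathways expected in ovaries, and markers of other tissues that a dissected ovary can carry (immune effectors and haemocyte genes, fat body, muscle, neuron, axoneme and sperm, cuticle, and serine proteases and digestive enzymes). Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists, and again with an estimated correlation and with fry. Each list's median was set against 10000 random lists of the same size matched on mean expression. The genes named are, first, the genes fixed in advance: MCM10, Mcm2 to Mcm7, vitellogenin, its receptor, ecdysone receptor, ultraspiracle, methoprene-tolerant, Krueppel homolog 1, vasa and PCNA. Second come the 10 largest rises and the 10 largest falls among changed genes whose groups did not overlap, with a mean FPKM of at least 5 in the higher group and an informative description. Last come, in each list, the 4 members with the smallest p, of which the text below names only some. No description in the table matched methoprene-tolerant. MCM10 was fixed because the title of the series names it as induced by mating, so its rise is not an independent test.

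Alternatives planned in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean FPKM of 5, median-ratio scaling, rescaling to TPM, quantile normalization, limma without trend and robust, array weights, replicate number as a block, and leaving out each library in turn. Added after seeing the data were limma's voom on the recovered reads, scaling to each library's own total, and lists without members that the words had matched by accident. Figures were drawn with matplotlib 3.10.9. Chorion genes and zinc finger genes belong to families of similar copies, and how reads shared between copies were assigned is not given in the sources used here.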

Results

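Plutella xylostella, the diamondback moth, is a pest of cruciferous crops whose females fill their eggs with vitellogenin, the yolk precursor protein. The study asked what mating changes in the ovary, with vitellogenesis and MCM10, a DNA replication factor, as its named subjects. Its title names MCM10 as induced by mating, so the direction of that change was known before the test. Expression was measured in ovaries of unmated and of mated females of the Geneva88 strain, in 3 libraries each. The recovered depth was 11915040, 10934960 and 12501272 reads in unmated replicates 1 to 3, and 12263131, 12043232 and 11754571 reads in mated replicates 1 to 3. The 20 genes with the most reads took 17.6 to 18.6% of the reads in unmated and 13.3 to 14.8% in mated libraries.

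The 6 libraries separated by mating. The first principal component of log2(FPKM + 1) held 69.3% of the variance, with scores of −25.3, −23.8 and −28.9 in the unmated and 8.17, 29.2 and 40.6 in the mated libraries. Correlations between libraries, across genes, were 0.986 to 0.989 among the unmated and 0.973 to 0.985 among the mated libraries, against 0.931 to 0.975 between the groups. Mated replicate 1 lay closest to the unmated libraries on this component.

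**Figure D1:**
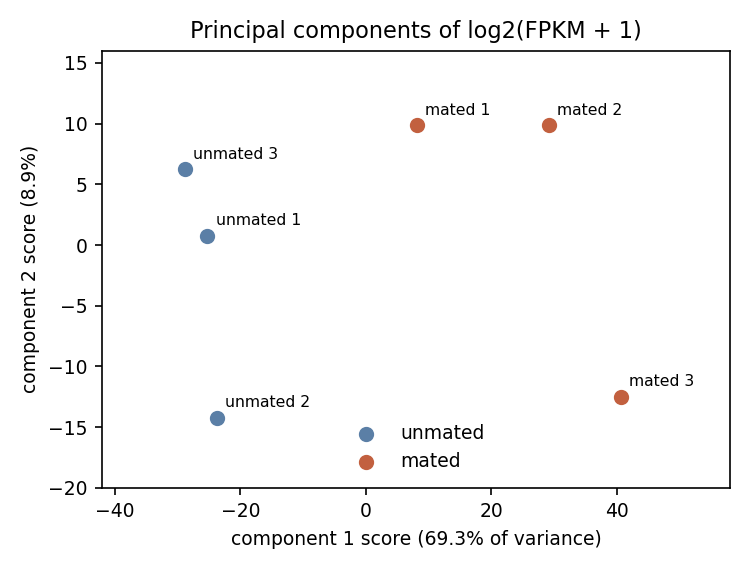
Scores of the 6 ovary libraries on the first (x axis) and second (y axis) principal component of log2(FPKM + 1), with the share of variance on each axis; each point is a library. The 3 unmated libraries lie between −28.9 and −23.8 on the first component and the 3 mated libraries between 8.17 and 40.6.

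MCM10 rose with mating while most subunits of the replicative helicase fell. MCM10 (LOC105393084, chromosome 3, 8932317 to 8935035, plus strand), which acts in the activation of replication forks, rose from 15.1 ± 0.462 FPKM in unmated to 35.3 ± 8.68 FPKM in mated ovaries (SD, n = 3 each). Its log2 fold change was 1.15 ± 0.18 (SE, limma adjusted p = 0.0027), and each mated library lay above each unmated one. The licensing factors Mcm2 to Mcm7, which form the core of the helicase, went the other way. Mcm7 (LOC105381146) fell from 84.1 ± 10.0 to 42.5 ± 7.28 FPKM (SD, n = 3, limma adjusted p = 0.0027). Mcm4 (LOC105391993) fell by 0.86, Mcm6 (LOC105382022) by 0.66, Mcm2 (LOC105389578) by 0.50 and Mcm5 (LOC105398439) by 0.40 on the log2 scale (limma adjusted p from 0.013 to 0.029), and PCNA (LOC105382745), the sliding clamp of the replication fork, fell by 0.38 (adjusted p = 0.031). Mcm3 (LOC105383935) had 17.0 ± 3.46 FPKM in unmated and 12.97 ± 4.21 FPKM in mated ovaries and did not pass (adjusted p = 0.18), but passed without mated replicate 1 (log2 fold change −0.63, adjusted p = 0.018). Leaving out single libraries ended several of these calls, at little changed sizes. Mcm5 did not pass without unmated replicate 1, 2 or 3 or mated replicate 2 (log2 fold changes of −0.36, −0.40, −0.45 and −0.35), nor Mcm4 without unmated replicate 1 or 3 or mated replicate 2 or 3 (−0.84, −0.81, −0.71 and −0.74). Mcm6 did not pass without unmated replicate 1 or mated replicate 2 (−0.58 and −0.60), Mcm2 without unmated replicate 2 or 3 or mated replicate 2 (−0.49, −0.47 and −0.50), nor PCNA without the same libraries as Mcm2 (−0.30, −0.37 and −0.37). The log2 ratio of MCM10 to the mean of Mcm2 to Mcm7, computed after these values were seen on the log2(FPKM + 1) scale, was −0.52 ± 0.05 in unmated and 1.26 ± 0.58 in mated ovaries (SD, n = 3, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). On the log2 FPKM scale, where a factor per library cancels, it was −0.53 ± 0.05 and 1.36 ± 0.63 (SD, n = 3, two-sided exact permutation p = 0.1). MCM10 ranked 231 among the 8406 tested genes by its rise. With values rescaled to TPM, MCM10 rose by 1.49 (adjusted p = 0.00023) and the falls of Mcm2, Mcm4, Mcm5, Mcm6 and PCNA no longer passed (adjusted p from 0.073 to 0.82), while Mcm7 still fell by 0.64. PCNA also fell by only 0.074 under quantile normalization (adjusted p = 0.63) and did not pass with no filter or without trend and robust (adjusted p = 0.055 and 0.060), nor Mcm5 with no filter or with replicate number as a block (0.050 and 0.056), and scaled to library totals the TPM losses recurred. Mcm3 passed with array weights (log2 fold change −0.52, adjusted p = 0.019).

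Vitellogenin and its receptor fell together. Vitellogenin (LOC105386528, chromosome 27, 188631 to 195708, minus strand) went from 5616 ± 671 FPKM in unmated to 2332 ± 470 FPKM in mated ovaries (SD, n = 3), a log2 fold change of −1.28 ± 0.17 (SE, limma adjusted p = 0.0023). A dissected ovary can carry fat body, and which tissue these transcripts came from was not tested. The fat body list, without members matched by accident, had a median log2 fold change of −0.32 over 8 genes (camera adjusted p = 0.19). The vitellogenin receptor (LOC105394312, chromosome 20), which takes yolk protein into the oocyte, went from 29.0 ± 0.857 to 16.4 ± 3.13 FPKM (SD, n = 3, limma adjusted p = 0.0044). Krueppel homolog 1 (LOC105392212), a transcription factor of the juvenile hormone response, fell by 0.49 on the log2 scale (adjusted p = 0.016), a call lost under TPM (adjusted p = 0.45), scaled to library totals (adjusted p = 0.21) and without unmated replicate 2 (log2 fold change −0.41, adjusted p = 0.074). The subunits of the ecdysteroid receptor did not pass: the ecdysone receptor (LOC105394159) had 8.10 ± 0.463 and 7.17 ± 1.51 FPKM, and ultraspiracle (LOC105388926) 18.3 ± 2.81 and 15.7 ± 2.46 FPKM, in unmated and mated ovaries. With array weights both passed (log2 fold changes of −0.39 and −0.36, adjusted p = 0.043 and 0.042). The germline helicase vasa (LOC105398159) had 366.6 ± 40.8 FPKM in unmated and 365.4 ± 24.6 FPKM in mated ovaries (adjusted p = 0.996), but was higher in mated ovaries by 0.34 on the log2 scale under TPM (adjusted p = 0.045) and under quantile normalization (adjusted p = 0.049).

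**Figure D2:**
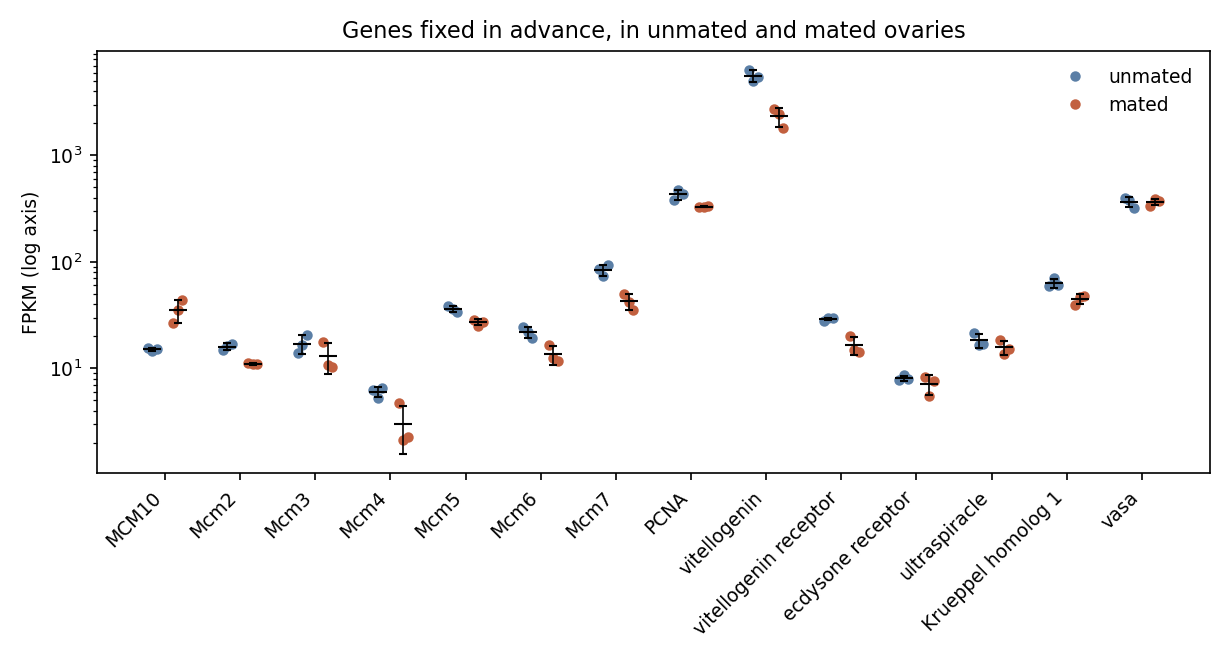
FPKM (y axis, log scale) of the genes fixed in advance (x axis) in each ovary library; points are libraries, the horizontal bars are group means and the error bars are SD over 3 libraries. MCM10 lies higher in all 3 mated libraries, at a mean of 35.3 against 15.1 FPKM, and vitellogenin lower, at 2332 against 5616 FPKM.

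Across the transcriptome, 3493 of 8406 tested genes changed (limma adjusted p under 0.05), 1888 higher and 1605 lower in mated ovaries. At least 2-fold changes were found for 593 genes, 443 of them higher. In 4584 tested genes (54.5%) all 3 mated values lay on one side of all 3 unmated values, against 10% by chance. The balance of rises and falls depended on the scaling between libraries. Rescaling to TPM moved the median log2 fold change of all genes from 0.01 to 0.30 and gave 2997 higher against 474 lower genes (1282 against 23 at least 2-fold), and scaling to library totals moved it to 0.23 and gave 2846 against 656 (1051 against 28). Quantile normalization left the median at −0.02, with 1695 higher and 1688 lower genes (291 against 215 at least 2-fold). Leaving out unmated replicate 3 gave 2239 changed genes. The 2-fold count was 1100 without mated replicate 1 and 351 without mated replicate 3.

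The largest rises with informative descriptions were of genes from many pathways. Cartilage-associated protein (LOC105385293) rose from 9.72 ± 2.53 to 34.1 ± 11.5 FPKM and Rac1 (ras-related C3 botulinum toxin substrate 1, LOC105384902), a small GTPase that regulates actin, from 26.0 ± 3.70 to 84.5 ± 27.4 FPKM (SD, n = 3 each, limma adjusted p = 0.0027 and 0.0023). A second gene described as Rac1 (LOC105384081) went from 31.4 to 37.97 FPKM and did not pass (adjusted p = 0.22). Mitochondrial NADPH:adrenodoxin oxidoreductase (LOC105386739), which passes electrons to mitochondrial P450 enzymes, rose 3.26-fold by the ratio of means, from 9.48 ± 0.568 to 30.9 ± 9.22 FPKM. The others were peroxisomal enoyl-CoA delta isomerase 3 (LOC105393934), an N-acetyltransferase 9 (LOC119691252), a homolog of testis-expressed protein 10 (LOC105388856), balbiani ring protein 3 (LOC105383738), subunit A of the enzyme that starts GPI anchor synthesis (LOC105386236), mpv17-like protein 2 (LOC105393792) and ubiquitin-related modifier 1 (LOC105396087), with log2 fold changes of 1.49 to 1.60. The largest falls were of a GCN1-like activator of eIF-2-alpha kinase (LOC125489096), from 8.17 ± 1.42 to 2.51 ± 2.38 FPKM, and the kinase LMTK3 (LOC119692686), from 7.83 ± 2.22 to 2.00 ± 0.695 FPKM (SD, n = 3, limma adjusted p = 0.0093 and 0.0027). Zonadhesin (LOC105389992) fell by 1.52 on the log2 scale. That call was lost, at little changed size, under TPM (log2 fold change −1.29, limma adjusted p = 0.055). It was also lost without unmated replicate 1, mated replicate 2 or mated replicate 3 (log2 fold changes of −1.25, −1.15 and −1.40, adjusted p from 0.054 to 0.084). The receptor Mth-like 1 (LOC119693713) went from 89.9 ± 12.6 to 32.6 ± 5.83 FPKM, general odorant-binding protein 56a (LOC105387994) from 32.1 ± 13.2 to 11.1 ± 3.998 FPKM and exonuclease GOR (LOC119690374) from 263.2 ± 38.4 to 98.8 ± 11.6 FPKM. Type I keratin 9 (LOC105382865) and the metalloproteinase ADAMTS14 (LOC105382158) each fell by 1.39. The carbohydrate enzymes glycogen debranching enzyme (LOC119690480) and a trehalase-like gene (LOC125488435), which release glucose from glycogen and trehalose, fell by 1.35 and 1.34.

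Genes of protein synthesis, protein turnover and respiration fell most broadly among the 27 lists. Of 77 cytosolic ribosomal protein genes, none rose and 58 fell (62 adjusted over the list alone), with a median log2 fold change of −0.60. Ribosomal protein L6 (LOC105382223) went from 2813 to 1501 FPKM and L18a (LOC105386767) from 3829 to 2088 FPKM. Of 65 translation and tRNA charging genes, 4 rose and 36 fell (4 and 38 adjusted over the list alone), among them subunits A, D and F of initiation factor eIF3 (LOC105397604, LOC105383132 and LOC105386332), which fell by 0.85, 0.94 and 0.73. Of 44 secretory pathway genes, 4 rose and 22 fell (5 and 25 adjusted over the list alone). Signal recognition particle subunit SRP68 (LOC105383134) fell by 1.14 and the chaperone endoplasmin (LOC119690418) by 0.95, whereas the 9 kDa signal recognition particle protein (LOC105387601) rose by 0.73. Of 40 proteasome genes, 2 rose and 23 fell (the same adjusted over the list alone). Proteasome subunit beta type-1 (LOC105390294) fell by 0.84, and non-ATPase regulatory subunit 7 (LOC105386307) rose by 0.88. Of 63 oxidative phosphorylation genes, 2 rose and 34 fell (2 and 36 adjusted over the list alone). ATP synthase subunits beta (LOC105384385) and gamma (LOC105384612) fell by 1.04 and 0.77. These counts depended on single libraries. Of the ribosomal proteins, 35 fell without unmated replicate 2 and 34 without unmated replicate 3, and of the proteasome genes 15 and 14. Of the secretory genes, 2 rose when any library but mated replicate 1 was left out, and 10, 11, 17, 14 and 14 fell without unmated replicate 1, 2 and 3 and mated replicate 2 and 3. Of the oxidative phosphorylation genes, 22, 20 and 15 fell without unmated replicate 1, 2 and 3, and 1 rose without unmated replicate 3 or mated replicate 2.

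Camera with a preset correlation called 10 of the 27 lists, all lower in mated ovaries, including these 5 (camera adjusted p from 3.04e-13 for the ribosomal proteins to 0.00034 for the secretory pathway). With an estimated correlation no list was called, and the adjusted p of these 5 lists was 0.57 to 0.60. The rotation test fry also called 10 lists: ribosomal proteins (adjusted p = 0.048), translation (0.038) and the proteasome (0.038), but not the secretory pathway (0.067) or oxidative phosphorylation (0.056), and 7 lists described below. The preset-correlation test called up to 14 lists when the 6 libraries were split in other ways. The tenth of tested genes with the highest expression (mean FPKM from 100.9) had a median log2 fold change of −0.33, with 113 genes higher and 366 lower. Random lists matched to the ribosomal proteins on expression had medians of −0.54 to −0.33 (central 95%), and the ribosomal median of −0.60 lay below that range. The medians of the rest of these 5 lists also lay below the ranges of their own matched random lists. Random lists draw genes independently, so these ranges do not allow for genes that move together. Under quantile normalization the ribosomal proteins had 7 genes higher and 8 lower, and the list's call was lost (adjusted p = 0.42). That method gives all libraries the same distribution of values, so a fall shared by the most highly expressed genes is reduced by construction. Under TPM 3 ribosomal protein genes were higher and 35 lower, against 12 and 17 for translation, 7 and 7 for the secretory pathway, 4 and 5 for the proteasome and 8 and 7 for oxidative phosphorylation. Relative to the median of all genes, the medians of the 5 lists lay below 0 under each scaling tried.

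**Figure D3:**
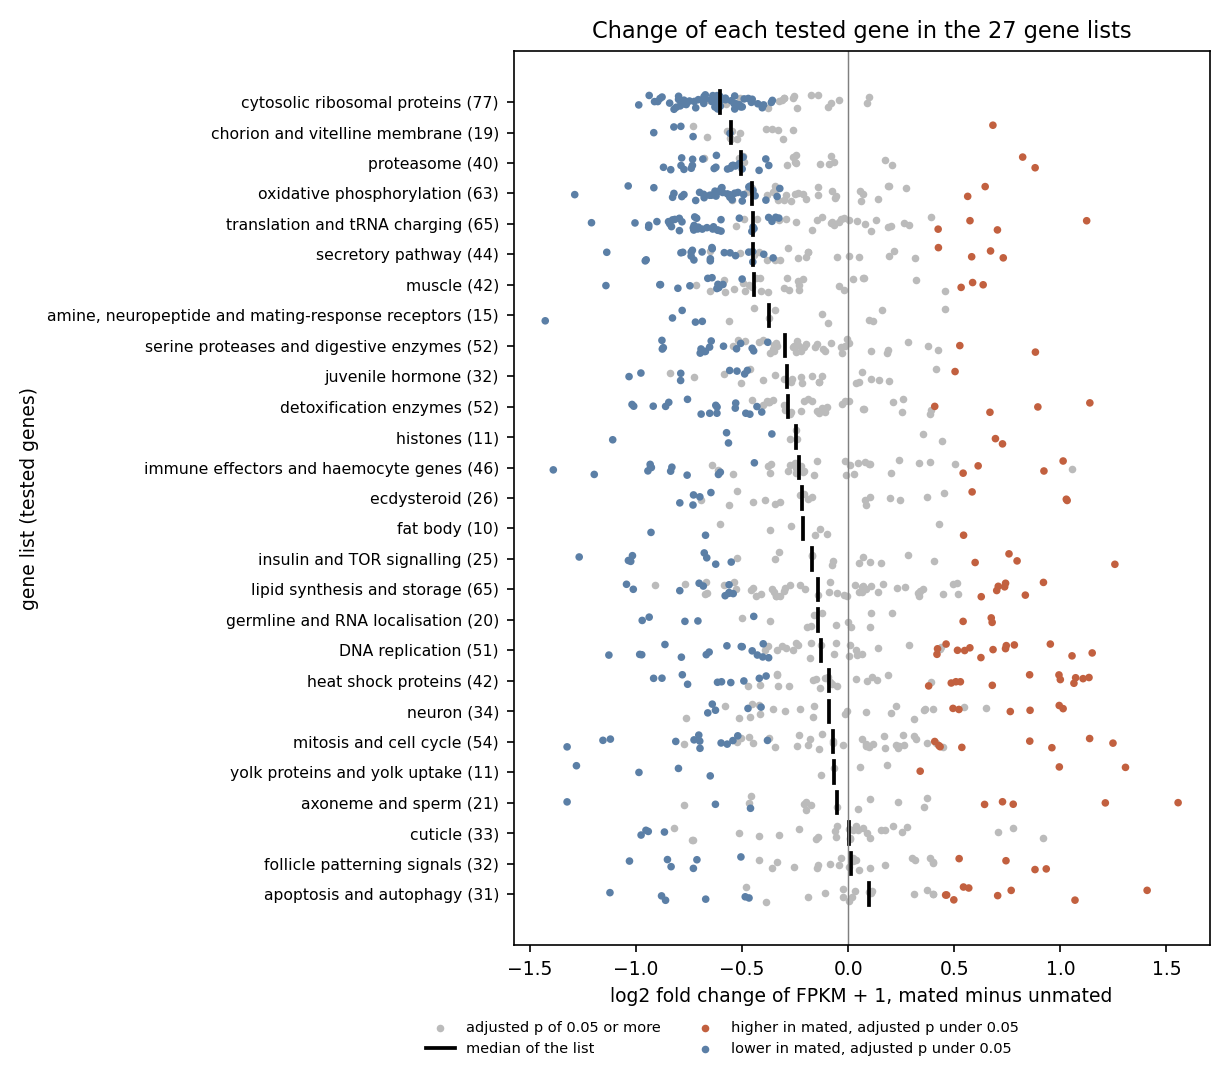
Log2 fold change of FPKM + 1, mated minus unmated (x axis), of each tested gene in the 27 gene lists (y axis, number of tested genes in brackets); points are genes, coloured by direction where the limma adjusted p was under 0.05, and black bars are list medians. The ribosomal proteins have the lowest median, at −0.60, and apoptosis and autophagy the highest, at 0.10.

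Genes of DNA replication and the cell cycle changed in both directions. Of 51 DNA replication genes, 14 rose and 15 fell (15 and 16 adjusted over the list alone). Besides MCM10, the catalytic subunit of DNA polymerase delta (LOC105385388) rose by 0.95 and subunit 4 of DNA polymerase epsilon (LOC105382516) by 1.05. Of 54 mitosis and cell cycle genes, 8 rose and 13 fell (the same adjusted over the list alone). The regulatory subunit of cyclin-dependent kinases (LOC105392284) rose by 1.25, transcription factor E2F5 (LOC105391776) by 1.14 and the spindle checkpoint protein MAD2A (LOC105380616) by 0.96, whereas ZNF207 (LOC105390114), a binding partner of the checkpoint protein BUB3, fell by 0.73. Of 11 histone genes, 2 rose and 4 fell (the same adjusted over the list alone): a histone H4 gene (LOC125488629) fell by 1.11 and an embryonic-type H1.1 gene (LOC105396937) rose by 0.69. None of these 3 lists was called by camera (adjusted p from 0.51 to 0.61). Under TPM the replication list had 19 genes higher and 3 lower, the mitosis list 17 and 4, and the histones 4 and 1. Without unmated replicate 1, 2 and 3 the replication list had 8 and 8, 9 and 6, and 6 and 5 genes higher and lower, and without mated replicate 2 and 3 it had 7 and 3, and 8 and 10. For the mitosis list these were 4 and 10 without unmated replicate 2, 4 and 7 without unmated replicate 3, 4 and 9 without mated replicate 2, and 4 and 11 without mated replicate 3. Without unmated replicate 3, 2 histone genes fell.

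Among egg-forming genes, yolk uptake and germline genes changed in both directions and most changed chorion genes fell under the deposited scaling. Of 11 genes of yolk proteins and yolk uptake, 3 rose and 4 fell (the same adjusted over the list alone), and the list was called by fry (adjusted p = 0.038) but not by camera (adjusted p = 0.69). For this list 3 rose and 2 fell without 3 members matched by accident. The AP-2 adaptor subunits alpha (LOC105394174) and sigma (LOC105384218), which load clathrin-coated pits, rose by 1.00 and 1.31, opposite to vitellogenin and its receptor. Of 19 chorion and vitelline membrane genes, 1 rose and 5 fell (the same adjusted over the list alone), with a median of −0.55 (camera adjusted p = 0.0046, and 0.72 with an estimated correlation). A chorion class A gene (LOC105393586) fell by 0.92, a call lost under TPM (adjusted p = 0.057), and chorion peroxidase (LOC105388487) rose by 0.68. That median lay inside the range of random lists matched on expression (−0.61 to −0.16, central 95%), fry did not call the list (adjusted p = 0.21), and under quantile normalization camera did not (adjusted p = 0.48) and no gene of the list passed. The number of chorion genes that fell was 1, 2 and 4 without unmated replicate 1, 2 and 3 (0, 1 and 0 rose), 11 without mated replicate 1, 3 without mated replicate 3 (where the list's median was −0.21) and 11 with replicate number as a block. Reads shared between chorion copies may make their individual values uncertain, since how such reads were assigned is not given. The chorion peroxidase call was also lost without unmated replicate 1 or 3 (log2 fold changes of 0.63 and 0.67, adjusted p of 0.070 and 0.063). Of 20 germline and RNA localisation genes, 3 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.38). The piRNA-binding protein Siwi (LOC105397264) went from 409.6 to 210.1 FPKM and pumilio (LOC105381096) fell by 0.71, whereas maelstrom (LOC105396147) rose by 0.68. Of 32 follicle patterning genes, 4 rose and 6 fell (4 and 5 adjusted over the list alone, camera adjusted p = 0.77). Bone morphogenetic protein receptor type-1B (LOC105384947) fell by 1.03, and Wnt-1 (LOC105397911), torso-like (LOC105380022) and Smad6 (mothers against decapentaplegic homolog 6, LOC105383145) rose by 0.93, 0.74 and 0.88. Under TPM the follicle list had 10 genes higher and 2 lower (8 and 2 scaled to library totals), the germline list 5 and 3 (4 and 3) and the yolk list 4 and 3 (4 and 3). The chorion list had 1 gene higher and 1 lower under TPM, and 1 and 2 scaled to library totals. Of the follicle genes, 3 rose and 3 fell without unmated replicate 1 or 2 or mated replicate 2. Of the germline genes, 3 fell when any library but mated replicate 1 was left out, and 8 without that one, while 2 rose without unmated replicate 3.

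Among hormone and nutrient pathways, the juvenile hormone, ecdysteroid, insulin and TOR, and lipid lists held more falls than rises, but more rises than falls under TPM. Of 32 juvenile hormone genes, 1 rose and 8 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.015, and 0.57 with an estimated correlation, fry adjusted p = 0.0465). A juvenile hormone epoxide hydrolase (LOC105389233) went from 17.5 to 8.06 FPKM and a juvenile hormone esterase (LOC105387899) from 40.7 to 20.1 FPKM. Another of each (LOC105386617 and LOC105385172) fell by 0.52 and 0.79, calls lost under TPM (adjusted p = 0.33 and 0.068). Under TPM 3 genes of that list were higher and 2 lower (3 and 3 scaled to library totals). Without unmated replicate 1, 2 and 3, 5, 6 and 5 genes fell, and none rose without unmated replicate 2 or 3 or mated replicate 2. Of 26 ecdysteroid genes, 3 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.30), and 2 rose and 3 fell without 3 members matched by accident. CYP315a1 (LOC105387501), a mitochondrial P450 enzyme of ecdysteroid synthesis, rose from 48.6 to 103.4 FPKM (limma adjusted p = 0.0037), and the ecdysone-inducible receptor E75 (LOC105384833) fell by 0.73, a call lost under TPM (adjusted p = 0.080). The ecdysteroid list had 6 genes higher and 1 lower under TPM and 5 and 2 scaled to library totals. Of its genes 1 rose without unmated replicate 3 or mated replicate 2, and 5 rose and 10 fell without mated replicate 1. Of 25 insulin and TOR signalling genes, 4 rose and 8 fell (the same adjusted over the list alone, camera adjusted p = 0.37, fry adjusted p = 0.049). Rheb (LOC105383012), the GTPase that activates TOR, rose by 1.26 and hamartin (LOC105388230), a subunit of the complex that inhibits Rheb, fell by 1.02. Under TPM and scaled to library totals, 6 genes of this list were higher and 3 lower, and 5 fell without unmated replicate 2 or 3 or mated replicate 3. Of 65 lipid synthesis and storage genes, 7 rose and 10 fell (5 and 8 adjusted over the list alone, camera adjusted p = 0.37). Lipase 3 (LOC119690582) went from 9793 to 4757 FPKM and the lipid droplet protein LSD-2 (lipid storage droplets surface-binding protein 2, LOC105384097) from 717.4 to 414.3 FPKM. The lipid list had 16 genes higher and 3 lower under TPM and 14 and 3 scaled to library totals. It had 5 and 4 without unmated replicate 1, 5 and 5 without unmated replicate 3, 3 and 9 without mated replicate 2 and 5 and 6 without mated replicate 3. Of 15 amine, neuropeptide and mating-response receptor genes, 0 rose and 5 fell (the same adjusted over the list alone, camera adjusted p = 0.066, fry adjusted p = 0.038). The furthest fall among them, by 1.43, was of general odorant-binding protein 56a (LOC105387994), which is a secreted carrier of odorants and not a receptor. Without unmated replicate 1, 2 and 3, 2, 3 and 2 of these genes fell, and 3 without mated replicate 2 or 3. Camera called the list without mated replicate 2 (adjusted p = 0.047), without trend and robust (0.048), under TPM (0.014) and scaled to library totals (0.0205). Under TPM 1 gene of the list fell, and 2 scaled to library totals.

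Stress and turnover genes went both ways. Of 42 heat shock protein genes, 12 rose and 10 fell (the same adjusted over the list alone, camera adjusted p = 0.80, median −0.09, mean 0.03), the smallest p values belonging to DnaJ proteins such as DNAJC21 (LOC105386100), which rose by 1.13. Of 31 apoptosis and autophagy genes, 9 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.62). Caspase-8 (LOC105390324) rose from 8.63 to 25.6 FPKM and autophagy-related protein 8 (LOC119690865) from 45.6 to 99.9 FPKM, whereas cathepsin B (LOC105390633) fell by 0.86. Of 52 detoxification genes, 4 rose and 17 fell (4 and 15 adjusted over the list alone, camera adjusted p = 0.010, 0.57 with an estimated correlation, fry adjusted p = 0.048), including cytochrome P450 4C1 (LOC105381031), which fell by 1.01. Under TPM the detoxification list had 7 genes higher and 6 lower, and the heat shock list 15 and 4. Of the detoxification genes, 11, 7 and 7 fell without unmated replicate 1, 2 and 3 (4, 2 and 2 rose), and 10 fell and 2 rose without mated replicate 2 or 3. Of the heat shock genes, 6 fell without unmated replicate 1. Of the apoptosis and autophagy genes, 5 rose and 4 fell without mated replicate 2, and 12 rose and 3 fell under TPM.

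Of the 7 lists of genes typical of other tissues, the muscle and serine protease lists were called, both lower in mated ovaries. Of 42 muscle genes, 3 rose and 12 fell (the same adjusted over the list alone), with a median of −0.45 (camera adjusted p = 0.00155, and 0.57 with an estimated correlation, fry adjusted p = 0.038). Muscle myosin heavy chain (LOC105388810) went from 83.7 to 38.2 FPKM and paramyosin (LOC105382673) from 55.0 to 29.8 FPKM, and the carnitine palmitoyltransferase (LOC105381350) that rose by 0.64 is a lipid enzyme named after muscle. Of 52 serine protease and digestive enzyme genes, 2 rose and 15 fell (1 and 14 adjusted over the list alone, camera adjusted p = 0.0044, and 0.57 with an estimated correlation, fry adjusted p = 0.039), a call lost with no filter (adjusted p = 0.20). Under TPM the muscle list had 5 genes higher and 5 lower, and the serine protease list 7 and 2. Of the muscle genes, 2 rose and 7 fell without unmated replicate 3, and 1 rose without mated replicate 2. None of the serine protease genes rose when any library but mated replicate 1 was left out, and 9, 8, 6, 7 and 11 fell without unmated replicate 1, 2 and 3 and mated replicate 2 and 3. Of 46 immune effector and haemocyte genes, 4 rose and 12 fell (the same adjusted over the list alone, camera adjusted p = 0.059, and 0.035 without members matched by accident), including a beta-1,3-glucan-binding protein (LOC105397355), which fell by 0.93. The ADAMTS metalloproteinases on that list (LOC105382158 and LOC125488965) are there only because their descriptions hold the word integrin. Camera called the immune list without unmated replicate 2 (adjusted p = 0.016) or mated replicate 2 (0.022) and under TPM (0.018), where 7 genes were higher and 7 lower. It also called that list scaled to library totals (0.021), under quantile normalization (0.046), with no filter (0.021), with a filter at a mean FPKM of 5 (0.026) and without trend and robust (0.048). Of 10 fat body genes, 1 rose and 2 fell (the same adjusted over the list alone, camera adjusted p = 0.38), and 0 rose and 2 fell without 2 members matched by accident. LOC119693854, with an unmated mean of 2368 FPKM, did not pass. It passed with replicate number as a block (log2 fold change −0.61, limma adjusted p = 0.010) and without mated replicate 2 (−0.89, 0.045). Apolipophorins (LOC105380513), the lipid carrier of the haemolymph, fell by 0.93. Of 34 neuron genes, 6 rose and 5 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.80), and of 33 cuticle genes, 0 rose and 4 fell (the same adjusted over the list alone, camera adjusted p = 0.37). In the neuron list 4 rose and 3 fell without 6 members matched by accident. Syntaxin-1A (LOC105386730) rose by 1.01, and the chitinase-like protein EN03 (LOC119694787) went from 611.3 to 335.9 FPKM. Camera called the cuticle list without mated replicate 2 (adjusted p = 0.047), with 7 genes lower, and 1 and 3 of its genes rose without mated replicate 1 and 3. The neuron list had 12 genes higher and 0 lower under TPM. It had 4 and 2, 5 and 2, and 3 and 3 without unmated replicate 1, 2 and 3, and 8 and 8, 3 and 2, and 3 and 2 without mated replicate 1, 2 and 3. Of the fat body genes, 1 fell without unmated replicate 1 or 3, none rose without the latter, and 2 rose without mated replicate 1. Of 21 axoneme and sperm genes, 5 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.80), but 15 of the 21 had been matched by an accident of wording, such as the testis-expressed protein 10 homolog (LOC105388856). Without those 15, 0 rose and 1 fell. The full list had 8 genes higher and 1 lower under TPM, and 1 lower without unmated replicate 2 or 3 or mated replicate 3. Median and mean differed in sign for the neuron (−0.09 and 0.004), cuticle (0.003 and −0.13), axoneme and sperm (−0.06 and 0.05) and follicle patterning lists (0.01 and −0.04).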

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

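Voom, scaling to library totals and the lists without members matched by accident were chosen after seeing the data. A count model planned only for a count table was not run. Median-ratio scaling equals the deposited scaling, so it tests nothing. The number of changed genes stayed within 1.5 times of 3493 except without unmated replicate 3 (range 2239 to 4247 over the libraries left out), and no gene changed in opposite directions between a setting and the reported test. The number changed at least 2-fold (593) was 908 with a pseudocount of 0.1, 1305 under TPM, 949 with voom, 1079 with library totals, and 351 to 1100 with single libraries left out. Of 27 lists, 0 were called with an estimated correlation and 9 to 13 in the other settings. MCM10, Mcm7, vitellogenin and its receptor passed in the same direction in each setting.

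Under TPM the log2 fold change was −0.072 for Mcm5, −0.34 for Mcm6, −0.19 for Mcm2, −0.63 for Mcm4, −0.16 for Krueppel homolog 1 and −0.037 for PCNA, none of which passed. With library totals these were −0.14, −0.40, −0.25, −0.65, −0.22 and −0.10, and none passed. These scalings raise the median of all genes, which by construction weakens falls. Vasa reversed from −0.00 to 0.34 under TPM (0.33765) and quantile normalization (0.33859), and PCNA (−0.074) no longer passed under the latter. Without a filter Mcm5 (−0.40) and PCNA (−0.38) no longer passed, as did PCNA (−0.38) in limma without trend and robust. With array weights Mcm3 (−0.52), the ecdysone receptor (−0.39) and ultraspiracle (−0.36) passed. The cause was not tested for the filter, quantile, trend and weight settings.

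Leaving out single libraries gave log2 fold changes of −0.45 to −0.35 for Mcm5, −0.80 to −0.56 for Mcm6, −0.63 to −0.25 for Mcm3, −0.56 to −0.47 for Mcm2, −1.14 to −0.71 for Mcm4, −0.54 to −0.40 for Krueppel homolog 1 and −0.46 to −0.30 for PCNA. Fewer libraries leave fewer degrees of freedom. The rule for named genes picked 135 single genes, not all of which are named above. Of these, 22 lost their call under TPM, 14 with library totals, 7 under quantile normalization and 5 to 10 without mated replicate 2 or 3 or an unmated library.

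With the replicate block, 3372 genes changed, 595 at least 2-fold, and 10 lists were called. Mcm5 (−0.40) no longer passed in that fit. Deviations of same-numbered libraries correlated at −0.005, −0.02 and −0.08 across genes, and no sample correlated best with its own number. Expression thus showed no pairing by number, but the labels do not say whether same-numbered libraries were prepared together. Counts of reads limit genes near the filter, where a mean FPKM of 1 rests on few reads.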

Other observations

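The gene families in these first paragraphs were tested after the data had been seen, as an exploration of 134 protein families with at least 10 tested genes. Camera called 10 families, 2 higher and 8 lower in mated ovaries, and none with an estimated correlation. Small GTPases of the Ras family, which steer membrane traffic and the actin skeleton, were higher in mated ovaries: of 51 tested, 21 rose and 2 fell (median log2 fold change 0.36, camera adjusted p = 0.0095, and 0.75 with an estimated correlation). A Rab21-like gene (LOC125491188) rose from 13.6 ± 0.692 to 40.1 ± 6.85 FPKM, Rab14 (LOC105387184) from 32.6 ± 4.01 to 65.3 ± 8.17 FPKM, and Rab11A (LOC105383794), of recycling endosomes, from 150.2 ± 22.01 to 263.2 ± 28.2 FPKM (SD, n = 3 each). Rab7a (LOC119691156) rose by 0.86 and Cdc42 (LOC105381592) by 0.88, whereas rhoC (LOC105382526) fell by 0.73, a call lost under TPM (adjusted p = 0.062). In the family 28 were higher and 0 lower under TPM, and 22 and 4 under quantile normalization. Without unmated replicate 1 or 3 or mated replicate 2 or 3, 1 fell. Zinc finger genes with the zf-AD domain, a large insect family of transcription factors, were the other higher family, with 40 of 90 up and 5 down (median 0.43, camera adjusted p = 0.0023, and 0.75 with an estimated correlation), but fry did not call the family (adjusted p = 0.073). Under TPM 52 were higher and 0 lower. Without unmated replicate 1, 2 and 3, 26, 31 and 28 rose and 1, 2 and 0 fell, and without mated replicate 2, 30 rose and 1 fell. The median was 0.27 without mated replicate 3, where 29 rose and 5 fell. The zf-AD genes are similar copies that can share reads.

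Of 15 bromodomain genes, whose proteins bind acetylated histones, 1 rose and 8 fell (camera adjusted p = 0.023, and 0.75 with an estimated correlation), with the acetyltransferase CREBBP (LOC105382489) going from 43.9 ± 0.421 to 18.4 ± 5.39 FPKM and polybromo-1 (LOC105389760) falling by 1.17. Under TPM 1 of them was higher and 2 lower, and scaled to library totals 1 and 3. Of these genes 4, 5 and 5 fell without unmated replicate 1, 2 and 3, 3 without mated replicate 2 and 6 without mated replicate 3, and none rose without any of these. Of 10 Hsp70 genes, 0 rose and 6 fell (camera adjusted p = 0.040, and 0.75 with an estimated correlation), among them Hsc70-4 (LOC105383306), from 9709 ± 1007 to 5653 ± 689.5 FPKM. Under quantile normalization the log2 fold change of Hsc70-4 was −1.9e-15. That method gives equal values to a gene of equal rank in each library, so it cannot test this fall. Of the Hsp70 genes, 3 fell under TPM and 3 scaled to library totals. The other lower families were proteasome subunits (11 of 14 fell and 0 rose, under TPM 1 and 1), trypsins (14 of 42 fell and 1 rose, under TPM 5 and 4), PCI domain proteins (9 of 16 and 0, under TPM 2 and 1), WD repeat proteins (23 of 51 and 5, under TPM 7 and 9), chorion proteins (5 of 14 and 0, under TPM 2 and 0) and ABC transporters (9 of 34 and 0, under TPM 1 and 4). Without unmated replicate 3, 7 proteasome subunits and 9 trypsins fell, and no trypsin rose without unmated replicate 1 or 3 or mated replicate 2 or 3, but 2 without mated replicate 1. Of the WD repeat genes, 14 fell without unmated replicate 2 and 15 without unmated replicate 1 or 3 or mated replicate 2 or 3, while 3, 1 and 2 rose without unmated replicate 2 and 3 and mated replicate 2. Of the chorion proteins, 2, 3 and 3 fell without unmated replicate 1, 2 and 3, 8 without mated replicate 1 and 3 without mated replicate 3. Of the ABC transporters, 5 fell without unmated replicate 1 or mated replicate 2, and 1 rose without mated replicate 1. Fry did not call the chorion proteins (adjusted p = 0.16).

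For the 3 patterns below, only the test of expression level and gene length and that of sperm transcripts were written before their results were seen. Of the tested genes, 41.6% changed with mating. The size of that number did not depend on the deposited scaling, since 3 other scalings gave 3383 or more changed genes. A scaling can also make calls of its own, so like counts cannot show that scaling made none of them. Which genes changed did depend on the scaling. Of the 3493 calls, 2362 were made in the same direction under TPM, 2544 scaled to library totals and 3006 under quantile normalization. Less of another tissue in the mated dissections may contribute to the falls. Muscle genes, without members matched by accident, had a median above that of the ribosomal proteins by 0.127 ± 0.0666 (bootstrap SE), too close to tell apart. That comparison is between lists that fell and does not address the 1888 genes that were higher. Whether the muscle transcripts came from the ovary or from another tissue was not tested. The bootstrap treated genes as independent, and muscle was picked as the lowest of the lists of other tissues. For the full muscle list and the ribosomal proteins, the medians were −0.43 and −0.07 under quantile normalization, but −0.17 and −0.26 under TPM. Their order thus depended on the scaling. An effect of mating, the contrast of the design, stays open beside less of another tissue. The labels do not give the age of the moths, or say whether the groups were prepared together. A difference of either kind between the groups could not be told apart from mating.

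Genes with little intron sequence were higher in mated ovaries. In the sixth of genes with 0 to 395 intron bases, 513 rose and 163 fell (median 0.28), against 173 and 268 in the sixth with the most (median −0.09). Genomic DNA would add a like FPKM to each gene, but 59.2% of all features had a mated mean below the median gain of 2.78 FPKM. This argues against an even addition of that size, while a smaller share of DNA was not tested. Within bins of expression and exon length the difference was 0.537 ± 0.0478 (bootstrap SE), against 0.37 without bins, so these do not account for it. The difference was 0.30 to 0.46 under the scalings and libraries left out that were tried, and was higher in each mated than in each unmated library (two-sided exact permutation p = 0.1, the smallest possible), while GC content was not tested.

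LOC105380114, an uncharacterized protein-coding gene (chromosome 3, 5386272 to 5388396, plus strand), had 0 reads in each unmated library and 990, 1072 and 980 reads in the mated ones, at least 820-fold higher against a floor of 3 reads over the group, which covers counting error only. The neighbouring cytochrome c gene (LOC105380115) had 7480, 6853 and 8290 reads in the unmated and 9006, 9541 and 8485 in the mated libraries. At the mean share seen in the mated libraries, its reads predict 771.6 or more reads in each unmated library. A leak of the same share in both groups thus cannot give the 0 reads found. A leak from that gene in the mated libraries only was not tested. Sperm transcripts stay open: the summed FPKM of axoneme and sperm genes was 0.821 times as high in mated as in unmated ovaries, but a baseline of 75.4 to 89.7 FPKM in unmated libraries would hide a small share, and the overlap of sums that was set in advance for a rejection was not found (67.9 to 68.2 FPKM in mated libraries). A genetic difference on chromosome 3 between the moths of the groups may be involved: of the 15 other genes with at least 5 reads in each library of one group and at most 3 reads over the other, 3 lie there, against 3.47% of features (Fisher's exact two-sided p = 0.014). That test was chosen after the locations were seen and those 3 genes are near the floor, so it is a hypothesis only, beside an effect of mating.

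The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The number of changed genes was as large as 3493 in 1 split, the real one, with at most 1 gene in the others, and the number changed at least 2-fold was as large as 593 in 1 split, again with at most 1 in the others. Each other split puts mated and unmated libraries on the same side. The difference between the groups then counts as spread within a side. Low numbers of genes were thus to be anticipated, and they do not weigh against chance. The number of lists called was as large as 10 in 4 splits, the real one included, with at most 14 in the others.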
